A study of Homo sapiens with 9 samples.

How the data were processed

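Gene expression was measured in HEY, an established human ovarian cancer cell line, in 9 libraries that form 3 groups of 3. The groups are the parental line, a line with a scrambled short hairpin RNA (shRNA) and a line with an shRNA against CIP2A. A short hairpin RNA is a transcript that the cell turns into a small interfering RNA, which lowers the mRNA it matches. Per the labels' protocols, the shRNA lines were transduced in the presence of polybrene, selected with puromycin and sorted for GFP where few cells carried it. RNA was isolated with a Nucleospin kit and libraries were made with the Illumina TruSeq Stranded mRNA protocol, per the same labels. The labels number the libraries of each group but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

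The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the size of the library), with 25268 genes and 1 column for each library. The unit was inferred from the values, which are not whole, are never negative and rise in steps set by gene and library. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3.0 and limma 3.46.0 were used with the hg19 genome. The program that made the FPKM values, its annotation and its use of strand are not given in the sources used here. Before the data were examined, a test for counts was planned, with limma on log2 values as the choice for a table of normalized values. The table held FPKM, so the second choice was used. 1 gene name that a spreadsheet had turned into a date was left out.

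The total depth of the libraries is unknown. In low genes the FPKM values are multiples of the value of 1 fragment, which gives depth relative to the first parental library. That relative depth was 1, 0.872 and 0.818 in the parental libraries, 0.873, 0.914 and 1.12 in the scrambled shRNA libraries, and 0.779, 1.17 and 1.05 in the CIP2A shRNA libraries. The ranges of the groups overlap. FPKM scales out depth, but a shallower library measures low genes and short transcripts less precisely. An exact 0 was treated with caution, because RPS27, a ribosomal protein gene that all cells use, is listed at 0 in 4 of the 9 libraries. Such genes are described as listed at 0, with the value of each library and no fold.

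Analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes that reached 1 FPKM in at least 3 libraries were kept, which left 11217. Values were put on the log2(FPKM + 1) scale, which understates the change of low genes. A model of the 3 group means was fitted to all 9 libraries, so that the groups share an estimate of the spread, with limma's moderated test and a trend of the variance with the mean. Adjusted p-values are Benjamini-Hochberg values over the genes tested, within each of 3 comparisons. A gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, and folds are ratios of mean FPKM. CIP2A was also tested with an exact permutation test of 3 libraries against 3.

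The genes named were set by a rule written before the data were examined. For each comparison with CIP2A shRNA and for the genes called the same way against both controls, it takes the 8 largest changes in each direction, and for scrambled shRNA against parental the 5 largest. These must be called, have a mean of at least 2 FPKM and show no overlap between the groups. The rule adds the 3 members of each gene list with the smallest adjusted p, list members given as examples, and genes set by name, among them CIP2A, MYC and E2F1. CIP2A is listed under its older symbol KIAA1524. XIST, Y-linked genes and some genes that the rule takes are not reported here.

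22 gene lists were fixed from textbook knowledge before the data were examined. They cover PP2A subunits and regulators, MYC target genes, E2F and DNA replication, G2/M and mitosis, p53 target genes, DNA damage repair, NRF2 targets and glutathione, NF-kB target genes, interferon response, mesenchymal and matrix genes, epithelial genes, stemness, MAPK pathway output, apoptosis and the BCL2 family, the unfolded protein and ATF4 response, hypoxia and glycolysis, cholesterol synthesis and oxidative phosphorylation. The other lists hold markers of haematopoietic, endothelial, fibroblast and mesothelial cells. Of 565 list entries, 554 matched the table by symbol and 11 by an older symbol. The 19 lists with at least 5 tested members were tested with camera (limma), which compares a list with all other genes, at a preset correlation of 0.01 between genes. Adjustment was over the 19 lists within a comparison. Where a count of called members is given, it is over all genes tested, with the count adjusted over the list alone beside it.

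Both comparisons of CIP2A shRNA share the CIP2A shRNA libraries, and other pairs of comparisons share a group too. The overlap of calls is given beside that of independent lists, which takes no account of this. The covariance of the log2 fold changes of 2 comparisons is therefore given beside 100 simulated data sets with no effect, and with a different library of the shared group in each comparison, a split added after the data were examined. The simulated errors of different genes were independent, so the simulated ranges may be too narrow. Tested genes were also placed in chromosome order with the gene positions of the GRCh38.p14 assembly, used only for names and neighbours because the table was made on hg19. Of the 11217 genes, 10962 were placed. A run of neighbouring genes was a stretch where the running median over 25 genes lay beyond the most extreme value of 100 shuffled orders against both other lines. This search was designed after the data were examined.

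The methods were tested on simulated data with 200 of 11217 genes changed. For CIP2A shRNA against scrambled shRNA, 55.2% of the genes changed by a log2 of 0.5 were recovered, 86.6% at 1 and 100% at 2, with 11 false calls of 172. For CIP2A shRNA against parental the shares were 70.1%, 95.5% and 100%, with 7 false calls of 184. For scrambled shRNA against parental they were 65.7%, 92.5% and 98.5%, with 9 false calls of 180. In 20 simulated lists with 11217 genes tested, the 1 list of 25 genes moved by 0.3 was called in each of the 3 comparisons and no other list was. In a simulation of CIP2A shRNA against both controls with 10962 placed genes, 60 neighbouring genes moved by -0.3 all fell in 1 run of 87 genes. No run was found with no change. In these simulations the error of each gene was drawn independently, so correlated genes, in lists or as neighbours, were not simulated. The genes called in the real data had median absolute log2 fold changes of 0.3753, 0.3615 and 0.3477 in the 3 comparisons. These lie below 0.5, the smallest change for which the recovery of single genes was simulated.

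The alternatives were quantile normalization, median-ratio scaling, no filter, a filter on the mean, limma without the trend, a pseudocount of 0.1, only the libraries of the groups compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library. Lists were also tested with an estimated correlation and with fry, a test of the list's genes alone. Leaving out short RNAs, and leaving out the genes in runs, were added after the data were examined. Planned count-based tests need counts and were not run. Across genes, the Pearson correlation of log2 values lay between 0.965 and 0.978 for the 9 pairs of libraries of the same group and between 0.960 and 0.974 for the 27 other pairs. Genes are not independent replicates, and no library repeated another.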

Results

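CIP2A is a protein that inhibits the phosphatase PP2A and is abundant in many cancers. The series asks about ovarian cancers with little CIP2A and their response to APR-246, an anticancer compound. No label names a drug treatment of the libraries analysed here, which set HEY cells with an shRNA against CIP2A beside 2 controls. The scrambled shRNA line went through the same transduction and selection, and the parental line did not. Sorting for GFP depended on how many cells carried it, so it may have differed between the 2 shRNA lines. Each group has 3 libraries. The 9 libraries had relative depths from 0.779 to 1.17 and each held between 10886 and 10982 genes at 1 FPKM or more, with 7.29% to 9.50% of the summed FPKM in the 10 highest genes. The values below are mean FPKM ± SD over 3 libraries.

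CIP2A mRNA was lower in the cells with the shRNA against it. Its level was 15.9 ± 0.596 FPKM in CIP2A shRNA cells, 27.1 ± 1.57 in scrambled shRNA cells and 25.5 ± 0.684 in parental cells (SD, n = 3). CIP2A shRNA cells thus kept 58.8% of the level in scrambled shRNA cells and 62.4% of that in parental cells. The log2 fold change was -0.73 against scrambled shRNA (SE 0.06, adjusted p = 0.000162) and -0.65 against parental (SE 0.06, adjusted p = 0.000502). The 2 controls were not called different, with a log2 fold change of 0.08 (adjusted p = 0.418). Every CIP2A shRNA library lay below every control library. The exact two-sided permutation p was 0.1 against each control, the smallest that 3 libraries against 3 allow. The levels of CIP2A, MYC and E2F1 in each library are shown in a plot of bars and points.

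**Figure D1:**
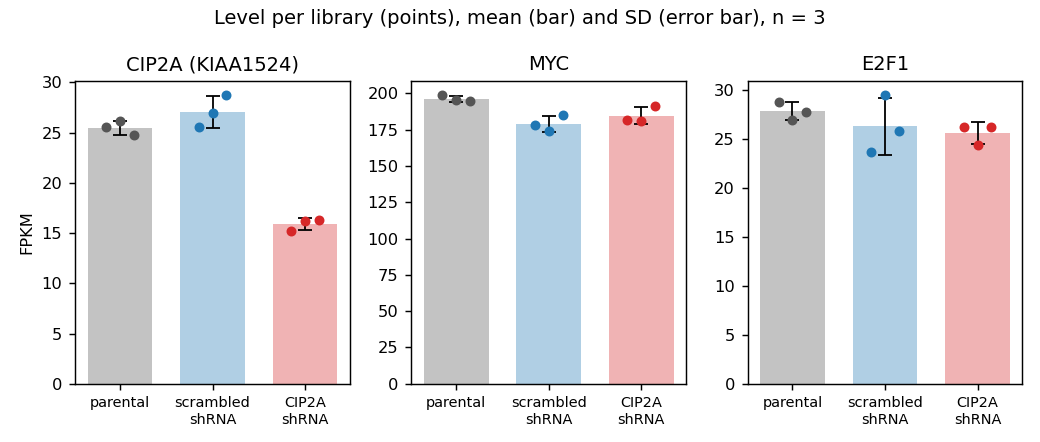
FPKM of CIP2A (listed as KIAA1524), MYC and E2F1 in the parental, scrambled shRNA and CIP2A shRNA lines. Points are libraries, bars the mean and error bars the SD over 3 libraries; CIP2A had a mean of 15.9 FPKM with CIP2A shRNA, 27.1 with scrambled shRNA and 25.5 in parental cells.

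MYC and E2F1, which encode transcription factors tied to growth and S phase entry, were not called in any of the 3 comparisons. MYC was at 185 ± 5.68 FPKM in CIP2A shRNA cells, 179 ± 5.65 in scrambled shRNA cells and 196 ± 2.06 in parental cells. Its log2 fold change was 0.04 against scrambled shRNA (adjusted p = 0.535) and -0.09 against parental (adjusted p = 0.225). E2F1 was at 25.6 ± 1.08, 26.3 ± 2.94 and 27.8 ± 0.91 FPKM in the same order, with log2 fold changes of -0.03 (adjusted p = 0.834) and -0.12 (adjusted p = 0.406). Its sign against scrambled shRNA turned without scrambled shRNA replicate 2, to 0.05, and without CIP2A shRNA replicate 2, to 0.00246.

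The comparison with scrambled shRNA asks what accompanies the CIP2A shRNA beyond transduction and selection. PRDX2, a peroxidase that removes hydrogen peroxide, was 8.63-fold lower in CIP2A shRNA cells, at 4.05 ± 0.285 against 35 ± 2.68 FPKM. The chemokine genes CXCL8 and CXCL1 fell with it, CXCL8 8.20-fold to 0.884 ± 0.229 FPKM and CXCL1 3.25-fold to 28.0 ± 2.3 FPKM. The matrix genes THBS1 (thrombospondin) and FN1 (fibronectin) were 4.03-fold and 3.18-fold lower. Among the genes that rose, LRRC17, which encodes a secreted leucine-rich protein, was 7.13-fold higher, at 12 ± 0.96 against 1.68 ± 0.571 FPKM. PPP2R2C, a regulatory B subunit of PP2A, was 5.50-fold higher, at 4.73 ± 0.302 against 0.859 ± 0.215 FPKM.

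In all, 1314 of 11217 genes were called between CIP2A shRNA and scrambled shRNA, 655 higher and 659 lower, and 63 of them changed by a log2 of at least 1. The 3 libraries of each group did not overlap for 31.1% of the tested genes, where chance gives 10%. With short RNAs and a pseudogene, given further on, set aside, the highest log2 fold changes past the naming rule were LRRC17 at 2.29 (adjusted p = 0.000106), the guanine deaminase gene GDA at 1.67 (adjusted p = 0.000145), the tight junction gene CLDN11 at 1.65 (adjusted p = 9.18e-07) and PPP2R2C at 1.63 (adjusted p = 0.000198). UNC13D, with a role in granule release, followed at 1.44 (adjusted p = 0.000678), then DTX3 at 1.42 (adjusted p = 0.00145) and ANKRD1 at 1.37 (adjusted p = 0.000145). With the same genes set aside, the lowest were PRDX2 at -2.83 (adjusted p = 9.07e-07), AJAP1, a gene of cell junctions, at -2.21 (adjusted p = 2.94e-05), the membrane scaffold gene MPP1 at -2.19 (adjusted p = 0.000191) and CXCL8 at -2.12 (adjusted p = 0.000141). Short RNAs also passed the rule: MIR1260B was listed at 0 in the 3 scrambled shRNA libraries and at 126, 85.2 and 81.9 FPKM with CIP2A shRNA. SNORA40, SNORA13 and SNORA23 were listed at 0 in the 3 CIP2A shRNA libraries. In scrambled shRNA cells SNORA40 was at 28.3, 162 and 110 FPKM, SNORA13 at 47.0, 44.9 and 18.2, and SNORA23 at 18.5, 11.8 and 4.79. The pseudogene HNRNPA1P10 (log2 fold change -3.32, adjusted p = 0.0209) shares sequence with HNRNPA1 and is uncertain. The calls of MIR1260B, the 3 small nucleolar RNAs and HNRNPA1P10 were lost without some single libraries, CIP2A shRNA replicates 1 and 3 among them for all 5. The count of genes fell to 804 without scrambled shRNA replicate 2, 692 without CIP2A shRNA replicate 2 and 819 without CIP2A shRNA replicate 3.

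Of 19 lists tested, 7 were called between CIP2A shRNA and scrambled shRNA. NF-kB target genes were lower: 9 of 20 fell, none rose, and the median log2 fold change was -0.37 (adjusted p = 1.71e-06, and adjusted p = 0.096 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. The inhibitor gene NFKBIA fell by 0.67 on the log2 scale (adjusted p = 0.00115), the cytokine gene IL1B by 0.90 (adjusted p = 0.00587) and the apoptosis inhibitor BIRC3 by 0.87 (adjusted p = 0.00115). Mesenchymal and matrix genes were lower, with 10 of 23 down and 2 up, 10 and 5 adjusted over the list alone (median -0.14, adjusted p = 0.00386, and adjusted p = 0.096 with an estimated correlation). Beside THBS1 and FN1, TGFBI was lower by 0.76 (adjusted p = 0.000538), CTGF by 0.38 (adjusted p = 0.00141) and LOXL2 by 0.42 (adjusted p = 0.00328). TGFBI was higher in scrambled shRNA cells than in both other lines. G2/M and mitosis genes were slightly lower, 5 of 24 down and none up, 10 and 1 adjusted over the list alone (median -0.12, adjusted p = 0.00179, and adjusted p = 0.274 with an estimated correlation). BUB1B changed by -0.23 (adjusted p = 0.00536) and UBE2C by -0.25 (adjusted p = 0.01). The mesenchymal and G2/M lists were called higher in scrambled shRNA than in parental cells (medians 0.11 and 0.17). Neither was called by camera between CIP2A shRNA and parental (medians 0.04 and 0.05, means -0.165 and 0.06). Fry called the mesenchymal list lower there (adjusted p = 0.000277) and did not call the G2/M list (adjusted p = 0.0525). Both calls against scrambled shRNA may owe part to the scrambled shRNA line, but for the mesenchymal list the 2 tests differ.

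NRF2 targets and glutathione genes were lower in the same comparison, 5 of 29 down and 2 up, 9 and 4 adjusted over the list alone (median -0.08, adjusted p = 0.0146, and adjusted p = 0.496 with an estimated correlation). The quinone reductase gene NQO1 was at 90.4 ± 0.845 against 147 ± 14.9 FPKM, a log2 fold change of -0.69 (adjusted p = 0.000538). GCLM, a subunit of the enzyme that starts glutathione synthesis, changed by -0.39 (adjusted p = 0.00286). Of the epithelial genes, 2 of 8 fell, 3 adjusted over the list alone, and none rose (median -0.15, adjusted p = 0.0146, and adjusted p = 0.271 with an estimated correlation). The claudin gene CLDN1 changed by -0.32 (adjusted p = 0.00466). p53 target genes were higher, 8 of 24 up and 1 down, 9 and 1 adjusted over the list alone (median 0.11, adjusted p = 0.0164, and adjusted p = 0.345 with an estimated correlation). RRM2B, a ribonucleotide reductase subunit, changed by 0.42 (adjusted p = 0.00113) and the death receptor gene FAS by 0.44 (adjusted p = 0.00396), while CDKN1A was at 0.03 (adjusted p = 0.761). Cholesterol synthesis genes were higher, 6 of 25 up and 1 down, 8 and 1 adjusted over the list alone (median 0.14, adjusted p = 0.00386, and adjusted p = 0.552 with an estimated correlation). LSS, which encodes lanosterol synthase, changed by 0.52 (adjusted p = 0.00728), at 14.2 ± 1.76 against 9.51 ± 0.147 FPKM, and lies in a run of neighbours that were higher together in this line. The p53 call was lost without CIP2A shRNA replicate 3 (adjusted p = 0.0563), and the NRF2 and epithelial calls without CIP2A shRNA replicate 1 (adjusted p = 0.0631 for both). The epithelial call also ended with no filter (adjusted p = 0.0751) and the cholesterol call under fry (adjusted p = 0.0511).

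The lists not called against scrambled shRNA had members in both directions or few called members. Of PP2A subunits and regulators, 2 of 24 rose, PPP2R2C and PPP2R2D (0.43, adjusted p = 0.0107), the second in a run of neighbours that were lower together in scrambled shRNA cells. The same 2 and no others were called adjusted over the list alone. The list had an adjusted p of 0.578, with a median of -0.05, a mean of 0.05 and a test statistic on the lower side. MYC target genes had 4 of 26 down and none up, 6 and 1 adjusted over the list alone (adjusted p = 0.0577). Fry called this list lower (adjusted p = 0.00146). E2F and DNA replication genes had 3 of 26 up and 2 down, as many adjusted over the list alone (adjusted p = 0.288), with CCNE2 at 0.31 (adjusted p = 0.00723) and RRM2 at -0.36 (adjusted p = 0.00136). DNA damage repair genes had 1 of 28 up and 1 down, and none either way adjusted over the list alone (adjusted p = 0.270). MAPK pathway output had 3 of 20 up and 4 down, 4 and 6 adjusted over the list alone (adjusted p = 0.578), with SPRY2 at 0.47 (adjusted p = 0.00587) and PHLDA1 at -0.50 (adjusted p = 0.00215). The adjusted p was 0.361 for the interferon response, 0.578 for stemness, 0.548 for apoptosis and the BCL2 family, 0.75 for the unfolded protein and ATF4 response, 0.906 for hypoxia and glycolysis, and 0.923 for oxidative phosphorylation. The median and mean of hypoxia genes had opposite signs (0.03 and -0.03), as did those of oxidative phosphorylation genes (-0.01 and 0.01). Among stemness genes the aldehyde dehydrogenase gene ALDH1A3 changed by -0.57 (adjusted p = 0.000313).

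The comparison with the parental line sets the CIP2A shRNA line against cells with no vector. FN1 fell 6.68-fold, from 151 ± 7.07 to 22.7 ± 1.11 FPKM. PRDX2 was 5.63-fold lower than its parental level of 22.8 ± 2.27 FPKM. ANKRD1, a gene of the cell's response to stretch, rose 3.78-fold from 2.78 ± 0.208 to 10.5 ± 1.51 FPKM. CSPG4, a cell surface proteoglycan gene, rose 2.78-fold from 2.45 ± 0.161 to 6.81 ± 0.391 FPKM. MYC target genes and NF-kB target genes were lower as groups, and p53 target genes higher. Of these 3 calls, that of MYC target genes held with an estimated correlation (adjusted p = 0.0114) and those of NF-kB (0.123) and p53 target genes (0.267) did not. MYC target genes were also lower in scrambled shRNA than in parental cells. Between CIP2A shRNA and scrambled shRNA camera did not call them (adjusted p = 0.0577), while fry called them lower (adjusted p = 0.00146).

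Of 11217 genes, 886 were called between CIP2A shRNA and parental, 430 higher and 456 lower, with 52 at a log2 change of at least 1. The groups did not overlap for 29.7% of tested genes, where chance gives 10%. With short RNAs, a pseudogene and a readthrough gene, given further on, set aside, the highest named log2 fold changes were FAM180A at 1.61 (adjusted p = 0.000486), ANKRD1 at 1.60 (adjusted p = 0.000107), LRRC17 at 1.59 (adjusted p = 0.00121), GDA at 1.51 (adjusted p = 0.000385), CSPG4 at 1.18 (adjusted p = 0.000123) and CLDN11 at 1.15 (adjusted p = 1.18e-05). With the same genes set aside, the lowest were FN1 at -2.69 (adjusted p = 1.39e-06), PRDX2 at -2.23 (adjusted p = 3.93e-06), MPP1 at -1.92 (adjusted p = 0.000639), AJAP1 at -1.89 (adjusted p = 0.000123) and the calcium-binding protein gene S100A1 at -1.86 (adjusted p = 0.00789). The pseudogene RPL13AP20 (1.37, adjusted p = 0.0126) and the readthrough gene SERF2-C15ORF63 (-2.68, adjusted p = 0.025) share sequence with other genes and are uncertain. SNORD57 was listed at 0 in the 3 parental libraries and at 1012, 337 and 375 FPKM with CIP2A shRNA. SNORD83B and SNORD21 were listed at 0 in the 3 CIP2A shRNA libraries, and in parental cells were at 194, 111 and 237 FPKM and at 176, 101 and 215 FPKM. The calls of these 3 and of SERF2-C15ORF63 were lost without some single libraries, parental replicate 1 and CIP2A shRNA replicate 2 among them for all 4. The count fell by more than 1.5 times without parental replicate 1 (380), 2 (438) or 3 (555) and without CIP2A shRNA replicate 1 (512) or 2 (405). It was 475 with the replicate number as a block, and 540 without the genes in runs of neighbouring genes described below.

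Of 19 lists, 5 were called between CIP2A shRNA and parental. MYC target genes were lower, with 4 of 26 down and none up, and 14 and none adjusted over the list alone (median -0.17, adjusted p = 8.68e-08). This call held with an estimated correlation (adjusted p = 0.0114). The nucleolin gene NCL was at 870 ± 76.6 against 1189 ± 39.9 FPKM, a log2 fold change of -0.45 (adjusted p = 0.00421), and it lies in a run of neighbouring genes that were lower together in this line. Its call was lost under quantile normalization. MYC target genes were also lower in scrambled shRNA cells against parental (median -0.10). They were not called by camera between CIP2A shRNA and scrambled shRNA (median -0.05), but were called lower by fry (adjusted p = 0.00146). In CIP2A shRNA cells against parental, NF-kB target genes had 8 of 20 down and 1 up, 10 and 2 adjusted over the list alone (median -0.32, adjusted p = 3.12e-05, and adjusted p = 0.123 with an estimated correlation). IER3 changed by -0.60 (adjusted p = 0.00303) and IL1B by -1.13 (adjusted p = 0.00332), while TNFAIP2 rose by 0.51 (adjusted p = 0.00473). NRF2 targets and glutathione genes had 7 of 29 down and 1 up, 15 and 3 adjusted over the list alone (median -0.17, adjusted p = 0.000207, and adjusted p = 0.267 with an estimated correlation). NQO1 changed by -0.44 (adjusted p = 0.00634). SOD1, the gene called higher, changed by 0.28 (adjusted p = 0.0115) and lies in a run of neighbours that were higher together.

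Unfolded protein and ATF4 response genes had 6 of 25 down and none up against parental, 8 and 1 adjusted over the list alone (median -0.12, adjusted p = 0.000394, and adjusted p = 0.267 with an estimated correlation). The amino acid carrier gene SLC7A5 changed by -0.46 (adjusted p = 0.00233), the transcription factor gene CEBPB by -0.56 (adjusted p = 0.00336) and STC2 by -0.46 (adjusted p = 0.00301). The list was lower in scrambled shRNA cells against parental too (8 of 25 down, median -0.15). It was not called between CIP2A shRNA and scrambled shRNA (median 0.02), so the fall against parental is not particular to CIP2A shRNA cells. In CIP2A shRNA cells against parental, p53 target genes had 6 of 24 up and none down, 7 and none adjusted over the list alone (median 0.14, adjusted p = 0.00103, and adjusted p = 0.267 with an estimated correlation). RRM2B changed by 0.43 (adjusted p = 0.0015), FAS by 0.42 (adjusted p = 0.00795) and CDKN1A, an inhibitor of cell cycle kinases, by 0.27 (adjusted p = 0.0102). Lists not called were PP2A subunits and regulators with 2 of 24 up and 1 down, as many adjusted over the list alone (adjusted p = 0.968), E2F and DNA replication (adjusted p = 0.202), G2/M and mitosis with 3 of 24 up, 5 adjusted over the list alone (adjusted p = 0.142), DNA damage repair (adjusted p = 0.239) and interferon response (adjusted p = 0.985). Mesenchymal and matrix genes had 6 of 23 down and 3 up, 6 and 5 adjusted over the list alone (adjusted p = 0.539), with a median of 0.04, a mean of -0.17 and a test statistic on the lower side. Epithelial genes had 3 of 8 down and 1 up, as many adjusted over the list alone (adjusted p = 0.0535), with the keratin genes KRT18 at -0.46 (adjusted p = 0.00238) and KRT8 at -0.40 (adjusted p = 0.00426). The adjusted p was 0.486 for stemness, 0.202 for MAPK pathway output, 0.721 for apoptosis and the BCL2 family, 0.138 for hypoxia and glycolysis, 0.150 for cholesterol synthesis and 0.138 for oxidative phosphorylation. Of these lists, fry called mesenchymal (adjusted p = 0.000277), epithelial (0.0125), hypoxia (0.0330) and stemness genes (0.0439) lower. Fry called MAPK pathway output higher (adjusted p = 0.0439). In the plot of list means, NF-kB target genes lie furthest below 0 in both comparisons with CIP2A shRNA.

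**Figure D2:**
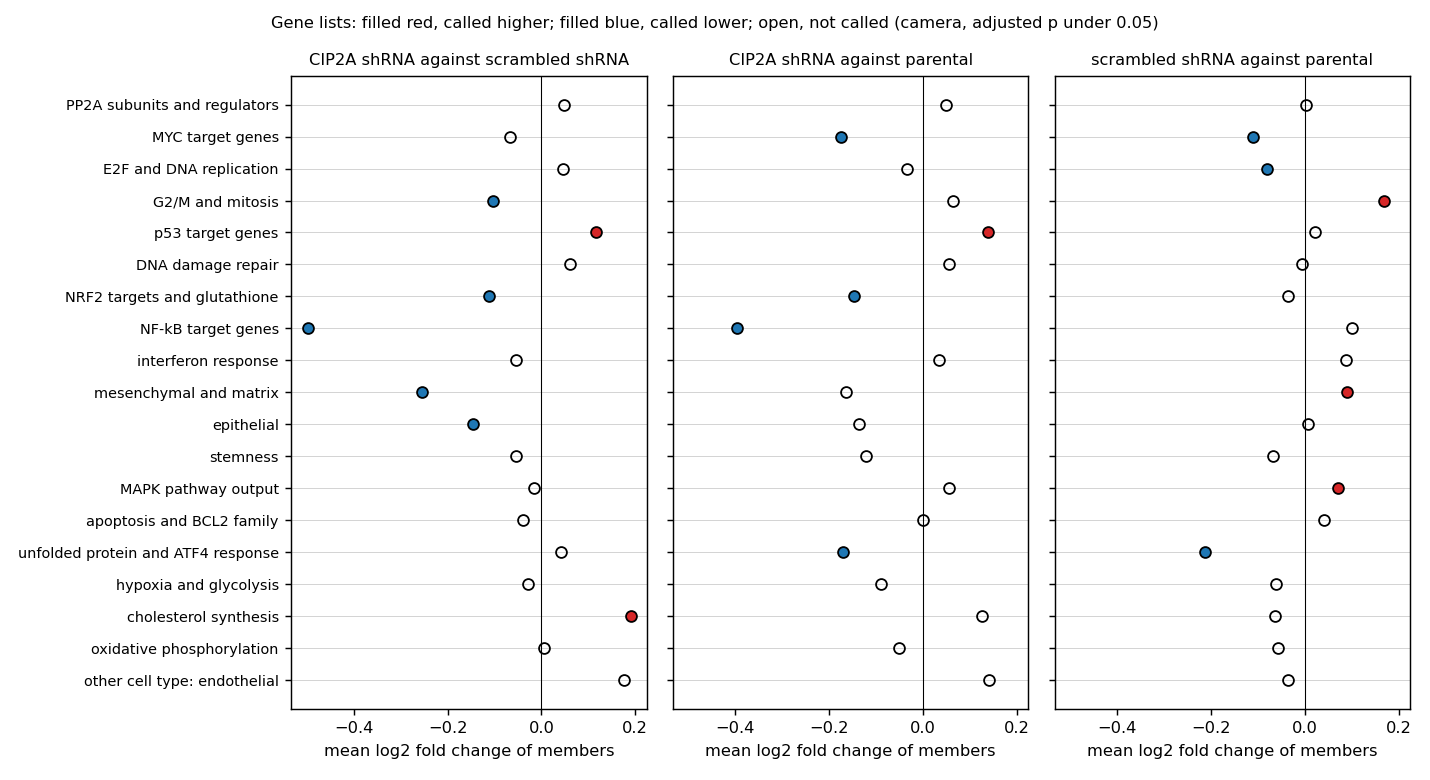
Mean log2 fold change of the tested members of each of 19 gene lists (horizontal axis, log2(FPKM + 1) scale) in the 3 comparisons. Filled red points are lists called higher by camera, filled blue points lists called lower and open points lists not called; 7, 5 and 6 lists were called from left to right.

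Genes called the same way against both controls separate changes of the CIP2A shRNA line from changes of a single control. All CIP2A shRNA libraries carry the label of the same shRNA. An effect of lower CIP2A therefore cannot be told apart from other effects of that shRNA or from other differences of that line. PRDX2, MPP1, AJAP1, FN1, ARMCX2, CXCL8, CXCL1 and THBS1 had the largest falls against both. MPP1 was at 0.536 ± 0.295 FPKM against 6.0 ± 1.34 and 4.74 ± 0.294 in scrambled shRNA and parental cells, and AJAP1 at 0.624 ± 0.18 against 6.47 ± 0.463 and 5.03 ± 0.832. ARMCX2 changed by -1.39 (adjusted p = 2.94e-05) and -1.79 (adjusted p = 9.92e-06). LRRC17, GDA, ANKRD1, FAM180A, CSPG4, CLDN11, PPP2R2C and UNC13D had the largest rises against both. GDA was at 19.5 ± 0.138 FPKM against 5.47 ± 0.912 and 6.27 ± 1.18, and PPP2R2C was 5.50-fold and 2.95-fold higher than in the 2 controls.

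In number, 433 genes were called the same way against both controls, 188 higher and 245 lower, and 11 were called in opposite directions. Independent lists of these sizes would share 25.1 higher and 26.8 lower genes, but part of the excess may come from the shared CIP2A shRNA libraries. Without short RNAs, the covariance of the 2 sets of log2 fold changes was 0.0365, against a mean of 0.00948 in simulations with no effect (range 0.00812 to 0.0111). With short RNAs included, it was 0.0655 against a simulated range of 0.0150 to 0.0595, and the correlation, at 0.606, lay within its simulated range of 0.238 to 0.707. With a different CIP2A shRNA library in each comparison, the covariance over the 6 pairs of libraries lay between 0.0216 and 0.0311 without short RNAs, and between 0.0187 and 0.0452 with them. The members of both directions are shown in a plot of the change against each control. NQO1, IER3, ALDH1A3 and the hypoxia gene ADM were among the genes called lower against both, and RRM2B, FAS, CCNG1 and ACTA2 among those called higher. ALDH1A3 was at 26.1 ± 1.54 FPKM against 39.3 ± 0.708 and 40.9 ± 0.428. The count moved by more than 1.5 times without parental replicate 1 (221), 2 (251) or 3 (288), scrambled shRNA replicate 2 (287), or CIP2A shRNA replicate 1 (270), 2 (207) or 3 (278). It was 249 with the replicate number as a block, and 260 without the genes in runs of neighbouring genes.

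**Figure D3:**
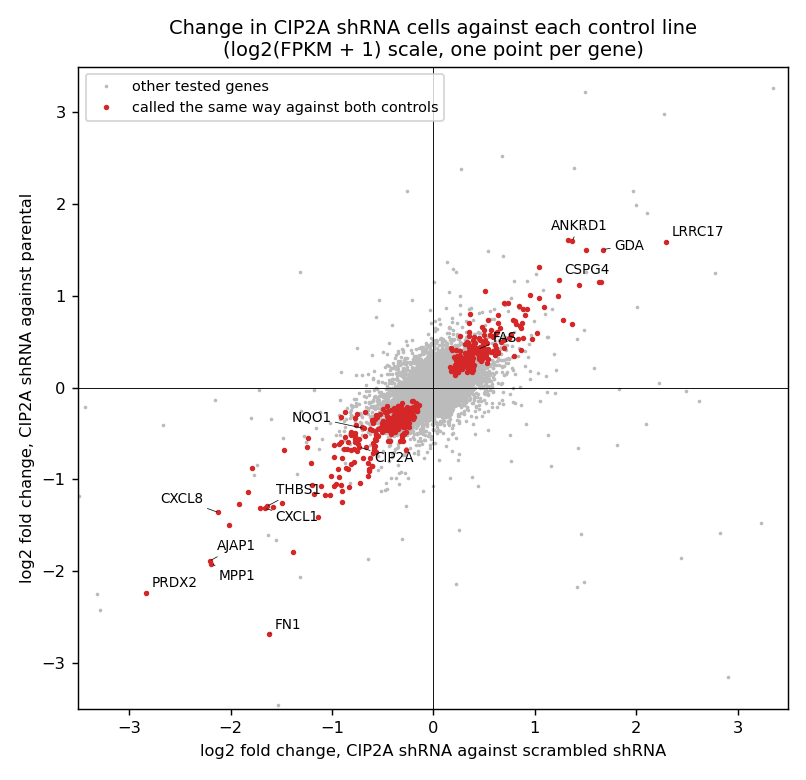
Log2 fold change of each tested gene in CIP2A shRNA cells against scrambled shRNA (horizontal axis) and against parental cells (vertical axis), on the log2(FPKM + 1) scale. Red points are the 433 genes called the same way against both controls and grey points the other tested genes; 20 genes lie outside the axes and none of them is red.

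The scrambled shRNA line differed from the parental line as well, with CIP2A not targeted. S100A2, a calcium-binding protein gene, was 2.47-fold higher in scrambled shRNA cells, at 40.3 ± 4.57 against 16.3 ± 2.49 FPKM. SERPINB7, a protease inhibitor gene, was 2.60-fold higher, and FN1 was 2.10-fold lower, at 72.2 ± 9.05 against 151 ± 7.07 FPKM. SHISA9 was 3.91-fold lower, at 2.05 ± 0.363 against 8.03 ± 0.403 FPKM. G2/M and mitosis genes were higher as a group, and unfolded protein and ATF4 response genes lower, but neither call held with an estimated correlation (adjusted p = 0.103 and 0.206).

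Between scrambled shRNA and parental, 816 genes were called, 431 higher and 385 lower, and 19 changed by a log2 of at least 1. The groups did not overlap for 29.5% of tested genes, where chance gives 10%. The highest named log2 fold changes were the telomerase RNA TERC at 1.49 (adjusted p = 0.0197), the hyaluronan synthase gene HAS2 at 1.34 (adjusted p = 0.0235), S100A2 at 1.26 (adjusted p = 0.00359), the uncertain pseudogene RPL13AP20 at 1.23 (adjusted p = 0.0235) and SERPINB7 at 1.19 (adjusted p = 0.00411). With the short RNA SNORA71C set aside, the lowest were SHISA9 at -1.57 (adjusted p = 0.000301), S100A1 at -1.22 (adjusted p = 0.0434), TMEM156 at -1.06 (adjusted p = 0.00821) and ELFN1-AS1 at -1.25 (adjusted p = 0.048), an antisense RNA whose reads cannot be told from its partner's without strand. SNORA71C was listed at 0 in the 3 scrambled shRNA libraries and at 17.7, 40.6 and 21.6 FPKM in parental cells. Without parental replicate 1 the calls of TERC, HAS2, S100A1, ELFN1-AS1 and SNORA71C were lost, and without parental replicate 2 that of RPL13AP20. The count was 220, 231 and 505 without parental replicate 1, 2 or 3 and 412, 298 and 346 without scrambled shRNA replicate 1, 2 or 3. It was 323 with the replicate number as a block, and 519 when only the 6 libraries compared were fitted.

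Of 19 lists, 6 were called between scrambled shRNA and parental, none with an estimated correlation. The estimated correlations of the MYC target and mesenchymal lists, -0.0275 and -0.0140, lay below the preset 0.01. Correlation between genes alone therefore cannot account for the loss of these 2 calls. G2/M and mitosis genes had 8 of 24 up and none down, 12 and none adjusted over the list alone (median 0.17, adjusted p = 2.81e-07, and adjusted p = 0.103 with an estimated correlation). NDC80, a kinetochore gene, changed by 0.40 (adjusted p = 0.00305) and the topoisomerase gene TOP2A by 0.32 (adjusted p = 0.00571). Unfolded protein and ATF4 response genes had 8 of 25 down and none up, 9 and none adjusted over the list alone (median -0.15, adjusted p = 0.000125, and adjusted p = 0.206 with an estimated correlation). The serine synthesis gene PHGDH changed by -0.67 (adjusted p = 0.0108) and SLC7A5 by -0.51 (adjusted p = 0.00253). MYC target genes had 4 of 26 down, 8 down and 1 up adjusted over the list alone (median -0.10, adjusted p = 0.00345, and adjusted p = 0.103 with an estimated correlation). Mesenchymal and matrix genes had 5 of 23 up and 1 down, the same adjusted over the list alone (median 0.11, adjusted p = 0.0116, and adjusted p = 0.103 with an estimated correlation), with TGFBI at 0.63 (adjusted p = 0.00305) and MMP2 at 0.70 (adjusted p = 0.00761). E2F and DNA replication genes had 2 of 26 up and 2 down, 2 and 5 adjusted over the list alone (median -0.10, adjusted p = 0.0214, and adjusted p = 0.458 with an estimated correlation), with MCM10, in a run of neighbours lower together in this line, at -0.44 (adjusted p = 0.00238). MAPK pathway output had 2 of 20 up, 6 up and 2 down adjusted over the list alone (median 0.06, adjusted p = 0.0439, and adjusted p = 0.267 with an estimated correlation). The E2F call was lost without parental replicate 1 (adjusted p = 0.0571), parental replicate 2 (0.0672) or scrambled shRNA replicate 3 (0.0621), and the MAPK call without parental replicate 1 (0.0571) or 2 (0.0672) or scrambled shRNA replicate 2 (0.0619) or 3 (0.149). The MAPK call also ended without short RNAs (0.0506) and without the genes in runs (0.0716).

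Lists not called between scrambled shRNA and parental included NF-kB target genes, with 5 of 20 up and none down, 6 and 1 adjusted over the list alone (adjusted p = 0.0539) and NFKBIA at 0.46 (adjusted p = 0.0108). The adjusted p was 0.735 for PP2A subunits and regulators, 0.639 for p53 target genes, 0.928 for DNA damage repair, 0.425 for NRF2 targets and glutathione, 0.384 for interferon response and 0.855 for epithelial genes. It was 0.855 for stemness, 0.368 for apoptosis and the BCL2 family, 0.0781 for hypoxia and glycolysis, 0.145 for cholesterol synthesis and 0.143 for oxidative phosphorylation. Of these lists, fry called NF-kB target genes (adjusted p = 0.0385) and apoptosis genes (0.0460) higher and hypoxia genes (0.0357) lower. KRT18 changed by -0.45 (adjusted p = 0.00411) and DSP, a desmosome gene, by 0.49 (adjusted p = 0.00771).

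Markers of other cell types were mostly too low to test. Haematopoietic markers had 1 of 20 tested, CD68, which was not called in any comparison, with log2 fold changes of 0.10, 0.27 and 0.17, but adjusted over the list alone was called higher in CIP2A shRNA cells than in parental cells. Endothelial markers had 6 of 15 tested and were not called as a list (adjusted p = 0.211, 0.257 and 0.855 in the order of the comparisons above). Against scrambled shRNA all 6 had positive log2 fold changes and none was called, nor adjusted over the list alone. Against parental, CIP2A shRNA cells had 2 up and none down, 3 and 1 adjusted over the list alone, with ROBO4 at 0.36 (adjusted p = 0.0349) and ENG at 0.19 (adjusted p = 0.0448), and scrambled shRNA cells had 1 up and none down, 1 and 2 adjusted over the list alone, with ROBO4 at 0.35 (adjusted p = 0.0436). The ROBO4 calls were lost without any 1 of the 6 libraries compared, and the ENG call without any parental replicate or CIP2A shRNA replicate 2 or 3. Fibroblast markers had 4 of 15 tested, with ACTA2 at 0.66 (adjusted p = 0.00191) and 0.65 (adjusted p = 0.00291) and FBLN1 at -0.70 (adjusted p = 0.00283) and -0.42 (adjusted p = 0.0348, a call lost without parental replicate 1 or 3 or any CIP2A shRNA replicate) in CIP2A shRNA cells against scrambled shRNA and parental. Mesothelial markers had 3 of 12 tested, with WT1 at -0.61 (adjusted p = 0.00197) and -0.46 (adjusted p = 0.0101) and the mesothelin gene MSLN, in a run of neighbours lower together in scrambled shRNA cells, at 1.19 (adjusted p = 0.00806) and 0.37 (adjusted p = 0.336).

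Called genes were not spread evenly along the chromosomes: of the 427 placed genes called the same way in CIP2A shRNA cells against both controls, 84 had an adjacent gene called the same way, and the highest of 1000 shuffled orders had 36 such genes. In the gene order of GRCh38.p14, 20 runs of neighbouring genes were higher or lower together in 1 line than in both others: 7 in CIP2A shRNA cells, 9 in scrambled shRNA cells and 4 in parental cells. The runs are not all separate: a run of CIP2A shRNA cells and one of scrambled shRNA cells share 36 genes from RBFOX2 to CBY1, and a run of scrambled shRNA cells and one of parental cells share 11 from RPUSD1 to TMEM204, which leaves 18 separate stretches. The clearest in CIP2A shRNA cells ran over 80 tested genes from DNPEP to D2HGDH, which includes NCL, and reached the end of a chromosome. Its median log2 fold change was -0.32 against scrambled shRNA and -0.33 against parental. Of the 80 genes, 70 were lower against both and 38 were called lower against both. From USP25 to MCM3AP-AS1, which includes SOD1 and LSS, 96 genes had medians of 0.25 and 0.20, and from TEF to RABL2B, which includes FBLN1, 73 genes had medians of -0.22 and -0.22. In scrambled shRNA cells, 63 genes from PRKX to MED14 had medians of 0.52 against CIP2A shRNA and 0.40 against parental. In parental cells, 140 genes from SSR3 to KIAA0226, which includes CLDN11, TERC and CLDN1, had medians of -0.22 against CIP2A shRNA and -0.17 against scrambled shRNA. The runs hold 9.05% of placed genes. Of the placed genes called between CIP2A shRNA and scrambled shRNA they hold 22.2%. For CIP2A shRNA against parental the share is 25.6%, and for scrambled shRNA against parental 19.9%. The runs of CIP2A shRNA cells hold 3.53% of placed genes, but 88 of the 427 called the same way against both controls (20.6%). The runs were found from the same log2 fold changes, so a higher share of calls in them is partly built in. The running medians along the chromosome that carries NCL are drawn in the plot of gene order.

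**Figure D4:**
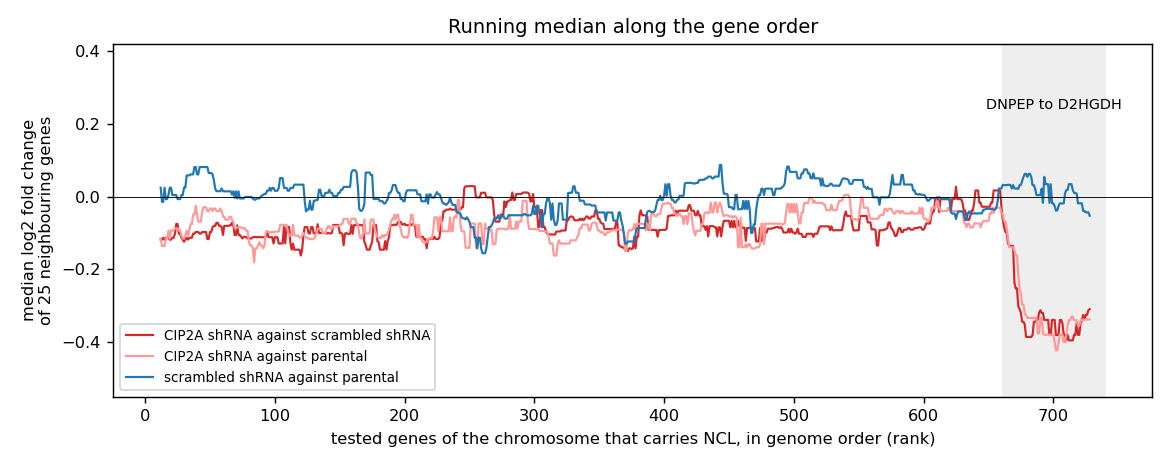
Running median of the log2 fold change over 25 neighbouring tested genes (vertical axis) along the chromosome that carries NCL, by rank in the gene order of GRCh38.p14 (horizontal axis), for the 3 comparisons. In the grey band from DNPEP to D2HGDH, with 80 genes, both comparisons of CIP2A shRNA drop together, to medians of -0.32 and -0.33, while scrambled shRNA against parental stays near 0.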

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

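CIP2A kept its direction and its side of the threshold in 48 of 48 alternatives over the 3 comparisons. Tests that need counts were not run on this table of FPKM. Of the called genes followed, 54 of 106 kept their call in every alternative for CIP2A shRNA against scrambled shRNA, 51 of 96 for CIP2A shRNA against parental and 21 of 77 for scrambled shRNA against parental, and 0 turned direction. E2F1, which was not called, ranged from -0.10 to 0.050 against scrambled shRNA with 1 library left out, and the cause was not tested. Requiring an absolute log2 fold change of 1 left 63, 52 and 19 genes in the same order and 31 against both controls, by construction. With 1 library left out, which leaves fewer samples, the counts ranged from 692 to 1029, from 380 to 613 and from 220 to 505, and from 207 to 383 against both controls. Fitting only the libraries compared gave 519 genes for scrambled shRNA against parental. Leaving out the genes in runs, an alternative chosen after seeing the data that tests fewer genes, gave 540 genes for CIP2A shRNA against parental and 260 against both controls, all of them called in the fit of all genes too. The runs hold 25.2% of the 886 genes called against parental, so some genes outside the runs also lost their call in this fit. With the replicate block the counts were 893, 475 and 323, and 249 against both controls. Same-numbered libraries did not deviate together throughout: 1 of 9 pairs had a correlation over 0.1, and the range was -0.142 to 0.126. As 3 libraries correlated best with their own number, the numbers are not treated as pairs. Same-numbered parental and CIP2A shRNA libraries had correlations of 0.0704, 0.0877 and 0.0459. The highest correlation, 0.195, joined different numbers: parental 1 with scrambled shRNA 2, and scrambled shRNA 1 with CIP2A shRNA 2. A batch shared by the groups under other numbers was not tested. List calls were 7, 5 and 6, and 0, 1 and 0 with an estimated correlation. Some of these calls were lost although the estimated correlation lay below the preset one, so such losses are not due to correlation alone. Fry, a test of other form, called 7, 10 and 9, and the block 7, 5 and 7.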

Other observations

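Of the hypoxia genes, ADM, which encodes the peptide adrenomedullin, was at 11.4 ± 1.3 FPKM in CIP2A shRNA cells, 19.1 ± 1.82 in scrambled shRNA cells and 20.2 ± 2.09 in parental cells, with log2 fold changes of -0.69 (adjusted p = 0.00375) and -0.77 (adjusted p = 0.00372). In the apoptosis list, BCL2L1, which encodes the survival protein BCL-XL, was at 153 ± 4.63 FPKM in CIP2A shRNA cells and 123 ± 7.25 in parental cells, a log2 fold change of 0.31 (adjusted p = 0.00795), and at 0.16 against scrambled shRNA (adjusted p = 0.0744). SLC7A11, the cystine carrier gene of the glutathione list, was at 2.12 ± 0.121 FPKM against 3.65 ± 1.17 and 4.26 ± 0.553, with log2 fold changes of -0.55 (adjusted p = 0.0589) and -0.75 (adjusted p = 0.025). The second call was lost without parental replicate 1 or 3, without any of the 3 CIP2A shRNA replicates and with no filter. Among genes in which scrambled shRNA cells stood apart, SHMT2, a serine and glycine enzyme gene, was at 144 ± 3.37 FPKM against 176 ± 2.85 with CIP2A shRNA and 178 ± 3.06 in parental cells. TGFBI was at 53 ± 2.54 FPKM in scrambled shRNA cells against 30.9 ± 2.89 and 33.9 ± 1.86.

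Of the tests that follow, those of chance splits, of regroupings and of adjacent called genes were set before the results were seen. Those of genes too low to test, of chance errors of the scrambled libraries and of short RNAs were chosen after. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real split called 1314 genes between CIP2A shRNA and scrambled shRNA, 886 between CIP2A shRNA and parental and 816 between scrambled shRNA and parental. In each case 1 of 10 splits, the real one, gave as many, and the highest other split called 2 genes. For lists, the real splits called 7, 5 and 6. As many were called in 1, 2 and 1 of 10 splits, with 3, 5 and 5 lists in the highest other split. Of 100 regroupings of the 9 libraries, 1, the real one, gave 433 genes called the same way against both other groups. The highest other gave 191 and kept 1 real group whole, which argues against a random grouping of these libraries as the source of this count. Each group is 1 line whose libraries may not be separate cultures. Regroupings therefore cannot tell an effect of the shRNA from chance differences between lines or cultures.

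The runs of neighbouring genes in all 3 lines may be gained or lost chromosome segments. Genes too low to be tested, which had no part in finding the runs, differed in the direction of the run in 16 of 20 runs, and in 15 of the 18 stretches left when runs that share genes are joined. A run held between 1 and 24 such genes, so in some runs the direction rests on few genes. Of the 427 placed genes called the same way against both controls, 84, or 19.67%, had an adjacent gene called the same way. In 1000 shuffled orders the mean was 16.7 genes and the highest 36 genes. By the rule set beforehand, a share under 20% counts against segments, and this share lay just below it. The count was nevertheless above that of every shuffled order, so for these genes segments cannot be told apart from other causes. Outside the runs of CIP2A shRNA cells, 32 of 339 called genes had an adjacent gene called the same way, a count made after the data were examined. The mean was 10.7 and the highest 24 in 1000 shuffled orders. No conclusion is drawn from this, because the search for runs selects these genes by how little their neighbours moved. DNA was not analysed here, and regulation shared by neighbouring genes was not tested.

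Between CIP2A shRNA and scrambled shRNA, 372 genes were called that were called the opposite way between scrambled shRNA and parental, where independent lists would give 25.3 and 22.5 in the 2 directions. The scrambled libraries enter both comparisons, so their errors push the 2 log2 fold changes of a gene apart. With a different scrambled library in each comparison, chance errors of single libraries would leave no covariance between them. Without short RNAs, which make up 2 of the 372 genes, it was -0.01796 on average over the 6 pairs of libraries (SD 0.00282, range -0.0218 to -0.0137), which argues against such errors as the whole cause. The 6 pairs are orderings of the same 3 scrambled libraries, so they are not independent and their SD does not measure the uncertainty of the mean. The covariance was taken over all tested genes other than short RNAs, not over the 372 alone. With short RNAs included, it ranged from -0.0197 to 0.0110. With all libraries in both comparisons, the covariance without short RNAs was -0.0280 against a mean of -0.00941 in 100 simulated data sets with no effect (range -0.0112 to -0.00771). With short RNAs included, it was -0.0471, within the simulated range of -0.0578 to -0.0186, as was the correlation, -0.481 (simulated range -0.670 to -0.261). A change of the scrambled shRNA line itself may account for these genes, as may an error common to its 3 libraries, and no test here separates the vector, the scrambled sequence and the growth of the line.

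Small nucleolar RNAs and microRNAs made up 34 of the 43 genes with an absolute log2 fold change of 2 or more between CIP2A shRNA and scrambled shRNA. Few fragments on short transcripts may account for this: the residual SD of the 100 tested short RNAs was a median of 19.88 times that of other genes of the same mean, and 79% of them were listed at 0 in at least 1 library. Of the 100, 6, 3 and 3 were called in the 3 comparisons and 0 the same way against both controls. No biological explanation was tested.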
